A study of Mus musculus with 2 samples.

How the data were processed

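Small RNA libraries from the midbrain of day 11.5 mouse embryos were analysed, 2 biological replicates of 1 group. The deposited tables hold raw read counts per microRNA gene, with a count regardless of strand, a count on the strand of the gene and a count on the opposite strand for each of 1973 genes. Per the notes deposited with the tables, the authors aligned to mm10 and used the GENCODE M4 annotation, and the aligner and its version are not given in the sources used here. No normalization had been applied to the counts, which are whole numbers with different totals. The count on the strand of the gene was the measurement, since adapter ligation to small RNA keeps the strand.

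The first 4 lines of each table name no gene and stayed out of library sizes and tests. Of 7655161 reads in replicate 1, 37.4% were in genes, 31.3% were unmapped, 25.0% aligned to several places, 6.35% lay outside genes and 0 were ambiguous. Of 18525114 reads in replicate 2 the shares were 31.1%, 33.6%, 26.2%, 9.16% and 0 reads. Reads that align to several places have a line of their own and were taken to be outside the gene counts, a handling that no source used here states, so counts of microRNAs with identical copies are uncertain. Counts on the opposite strand were 2.82% and 2.72% of the reads over both strands. A count of 3 reads, used as the limit for a gene without reads, was 1.05 CPM in replicate 1 and 0.521 CPM in replicate 2. Molecular identifiers are not described in the sources used here.

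Gene names, positions and hairpin sequences were taken by identifier from GENCODE M21 on GRCm38, the same assembly as mm10. A hairpin was called exonic if it overlapped an exon of any annotated transcript of its host gene. It can be intronic in other transcripts of that gene. An entry was found for 1894 of the 1973 genes, 1815 with the same version, and the 79 others held 7 reads in both libraries together. Hairpins that share an identical stretch of 20 bases with another hairpin numbered 923 of 1894. CPM was computed over the reads in microRNA genes of a library, and log2 values used a pseudocount of 1. A gene was detected with 10 or more reads in each library. Genes named in the text were, by a rule fixed before the data were examined, the 20 with the highest mean CPM, up to 4 detected members of each list, the 5 with the largest ratio between the libraries among genes with a mean count of 100 or more that differed, and up to 4 members of each of 3 clusters. Exceptions are stated.

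Lists of microRNA genes were fixed before the data were examined, 18 lists with 188 entries, of which 169 were matched, 3 of them by a letter suffix. They cover neural, glial, let-7, Mir125 and Mir99, Mir17 cluster and paralogs, pluripotency, Dlk1-Dio3, Hox-embedded, erythroid, leukocyte, endothelial, mesenchymal, muscle, epithelial, sensory, choroid plexus and pigment epithelium, ciliated, and liver and pancreas microRNAs. The lists do not overlap. The other-tissue set joins the lists named from Hox-embedded on. The difference between the neural and the other-tissue median was taken per library, and list medians were set among 10000 random lists of the same size, as a description.

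With 1 group there is no contrast, so no quasi-likelihood test and no test between groups was possible, and chance splits and outliers among samples do not apply. The libraries were compared gene by gene with a two-sided exact conditional binomial test on counts, with effective library sizes from edgeR's TMM factors (1.02 and 0.978) and Benjamini-Hochberg adjustment at 0.05 over genes with 10 or more reads in sum. The biological coefficient of variation was estimated with edgeR's estimateDisp and an intercept-only design, with 100 bootstrap draws over genes. Neighbouring detected hairpins of a strand within 10 kb formed clusters, and their differences were set against 10000 random pairings.

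Alternatives were the count regardless of strand, hairpins without a shared stretch, other count minimums, pseudocounts of 0.5 and 5, total-count and DESeq2 scaling, detected members only, cluster distances of 3 and 50 kb, and leaving out each replicate. The tests were first run on simulated data. In 525 genes drawn from the real means, 75.0% of 100 genes changed 2-fold and 100% of 100 changed 4-fold were called, with 1.54% of 325 unchanged genes. These counts had counting error only and known library sizes. The rates therefore do not hold for libraries that also vary as biological replicates do. A simulated coefficient of variation of 0.2 was estimated at 0.189. Software was R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.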

Results

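MicroRNA sequencing was carried out on total RNA from the midbrain of B6NCrl mouse embryos at day 11.5, with inserts under 30 bases. The labels give 1 group of 2 biological replicates, each a pool of male and female tissue, from 109 embryos in replicate 1 and 88 in replicate 2. The tables assigned 2859634 reads to microRNA genes in replicate 1 and 5754277 in replicate 2, so replicate 2 was 2.01 times as deep. Levels are given as CPM, the reads of a gene scaled to the reads counted in microRNA genes, or as a percent of those reads. A microRNA gene is the hairpin from which the mature strands are cut, and the counts do not separate the strands. With a single group there was no comparison between conditions, and the measurements below describe the profile of the tissue and the spread between the replicates.

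The first question was which microRNAs make up the profile of the embryonic midbrain. Mir99a (ENSMUSG00000065530.1) had the highest level, with 10.02% ± 1.13 of the reads (SD, n = 2). It lies on chromosome 16 at 77598936 to 77599000 (mm10), in an intron of the noncoding host gene Mir99ahg. Mir335 (ENSMUSG00000065501.1), in an intron of the imprinted gene Mest on chromosome 6 at 30741299 to 30741396, followed with 7.52% ± 0.724. Mir17 (ENSMUSG00000065508.1), a founding member of a cluster known for promoting proliferation, had 6.14% ± 0.814 and lies in an exon of Mir17hg on chromosome 14 at 115043671 to 115043754. Mir130a, intergenic on chromosome 2 at 84741115 to 84741178, had 3.81% ± 0.206. Mir126a, an endothelial microRNA within Egfl7 on chromosome 2 at 26591357 to 26591429, had 3.38% ± 0.209. It overlaps an exon of at least 1 annotated Egfl7 transcript and can be intronic in others.

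The 10 highest genes held 44.3% ± 1.03 of the reads (SD, n = 2), and the 20 highest held 58.8% ± 1.75. In replicate 1 the 10 genes held 43.5% (95% Wilson interval 43.5% to 43.6%) and in replicate 2 45.0% (44.9% to 45.0%), so that the libraries differed by more than counting error. Mir99b, in an intron of Spaca6, had 3.24% ± 0.282 and Mir100, in an intron of 3110039I08Rik, had 2.98% ± 0.437. Mir20a of the Mir17 cluster had 2.68% ± 0.324. Mir30e, in an intron of Nfyc, had 2.63% ± 0.240. Mir93, which overlaps an exon of at least 1 annotated transcript of the replication factor gene Mcm7, had 1.86% ± 0.163. Mir92b and Mir26b had 1.86% ± 0.00229 and 1.79% ± 0.319, and Mir322 and Mir106b had 1.74% ± 0.155 and 1.66% ± 0.109. Mir744, Mir18, Mirlet7g, Mir30a, Mir143 and Mir130b completed the 20, down to 1.10% ± 0.108 for Mir130b. Of these 20 hairpins, 10 lie in introns, 5 overlap an exon of at least 1 annotated transcript of their host and 5 lie between genes. None shares a stretch of 20 bases with another hairpin, against 95 of the 403 detected genes. Reads that align to several places were taken to be outside the gene counts. The ranking and percents thus cover reads with 1 place only, and microRNAs with identical copies may rank too low.

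In all, 403 of the 1973 microRNA genes were detected with 10 or more reads in each library, 409 in replicate 1 alone and 466 in replicate 2 alone. A gene without a read could still be present at up to 1.05 CPM in replicate 1 and 0.521 CPM in replicate 2, the level of 3 reads. These floors do not hold for hairpins with identical copies, whose reads may lie among those that align to several places. Intervals and these floors cover counting error only, since amplified reads are not independent molecules.

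The second question was which tissue's microRNAs were high, and it was addressed with lists fixed before the data were examined. In the neural list, 23 of 24 measured members were detected, and together they held 3.67% ± 0.109 of the reads (SD, n = 2). Mir92b, found in neural progenitors, had 18610.9 ± 22.9 CPM, Mir149 9139 ± 372 CPM, Mir153 3547 ± 95.8 CPM and Mir137, a regulator of neuronal differentiation, 2954 ± 384 CPM. Of the textbook brain microRNAs, the highest measured copies were Mir124a-2 with 33.4 ± 8.73 CPM and Mir9-3 with 149 ± 23.4 CPM, against a median of 152 ± 8.91 CPM for detected genes. The other copies were lower, with 6.99 and 1.22 CPM in replicates 1 and 2 for Mir124a-1, 6.99 and 5.39 CPM for Mir124a-3, and 5.25 and 3.82 CPM for Mir9-2. All of these were named after their values were seen, and Mir9-1 was not analysed here. Mir124a-2 and Mir9-3 are among the 17 neural members whose hairpin shares 20 bases with another hairpin, and the tables list reads that aligned to several places on a line apart from the genes.

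The median of the neural list was 135 ± 14.02 CPM, against 77.3 ± 6.43 CPM for the 54 measured members of the other-tissue lists together. The difference of the medians was 0.80 ± 0.01 on the log2(CPM + 1) scale (SD, n = 2) and positive in both libraries. It depended on how members were chosen. Among the 23 neural and 44 other-tissue members that were detected it was -0.16, and among the 7 and 43 members without a shared stretch it was 4.18. Taken singly, several other-tissue lists had a higher median than the neural list. These were endothelial (33785 CPM), sensory (1686 CPM), liver and pancreas (314 CPM), epithelial (287 CPM) and mesenchymal (236 CPM). The Hox-embedded, erythroid, leukocyte, muscle and ciliated medians were lower. The choroid plexus and pigment epithelium median was higher in CPM but lower on the log2 scale. In each library the median of the neural list exceeded that of all 10000 random lists of annotated genes (percentile 100). This says little about neural microRNAs, since most annotated genes were not detected. The Hox-embedded list reached percentiles of 96.7 and 96.3 and the muscle list 97.9 and 98.6 in replicates 1 and 2. Against random lists of detected genes the detected neural members were at the percentiles 48.3 and 45.4.

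Among the lists tied to growth and development, 3 held more reads than the neural list as counted. This order is uncertain, since 17 of the 24 neural members share a stretch of 20 bases with another hairpin and may have lost reads. Such members numbered 2 of 6 in the Mir125 and Mir99 list, 4 of 15 in the Mir17 list, 4 of 45 in the Dlk1-Dio3 list and 5 of 10 in the let-7 list. The 6 members of the Mir125 and Mir99 families, all detected, held 17.2% ± 1.77 of the reads, with Mir99a, Mir99b and Mir100 ahead of Mir125a at 6154 ± 960 CPM. The 15 members of the Mir17 cluster and its paralogs, all detected, held 16.7% ± 1.35, led by Mir17, Mir20a, Mir93 and Mir106b. In the imprinted Dlk1-Dio3 region 43 of 45 members were detected and held 6.87% ± 0.368, with 8675 ± 685 CPM for Mir487b, 7449 ± 1467 CPM for Mir411, 6398 ± 736 CPM for Mir431 and 5321 ± 1930 CPM for Mir541. All 10 measured let-7 members, which are known to accumulate as cells differentiate, were detected with 2.00% ± 0.279 of the reads, with 12349 ± 1877 CPM for Mirlet7g, 5037 ± 649 CPM for Mirlet7i, 1402 ± 106 CPM for Mirlet7d and 679.8 ± 123 CPM for Mir98. The pluripotency list had 9 of 12 members detected and 0.962% ± 0.102 of the reads. Its highest members were Mir302d with 3196 ± 281 CPM, Mir302a with 3068 ± 380.2 CPM, Mir302b with 2754 ± 318 CPM and Mir302c with 387 ± 31.9 CPM. The 3 glial members held 0.891% ± 0.0141, with 7322 ± 99.7 CPM for Mir219a-2, 1468 ± 235 CPM for Mir219a-1 and 121 ± 5.33 CPM for Mir338.

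MicroRNAs of the lists named for other cell types were also counted. Without a reference tissue, their levels do not show that these cell types were present. Mir126a, the measured member of the endothelial list, had 33785 ± 2087 CPM. The mesenchymal list held 2.21% ± 0.0504 of the reads with 7 of 8 members detected, among them Mir143 with 11068 ± 359.7 CPM, Mir214 in an exon of Dnm3os with 5764 ± 131 CPM, the cartilage microRNA Mir140 with 4740.1 ± 92.9 CPM and Mir199b with 309 ± 55.0 CPM. The 3 members of the sensory list held 0.469% ± 0.0153, with 1994 ± 540 CPM for Mir182, 1986 ± 320.4 CPM for Mir183 and 707 ± 66.1 CPM for Mir96. All 7 epithelial members were detected with 0.273% ± 0.00827, led by the skin microRNA Mir203 with 1130 ± 4.26 CPM, Mir205 with 771 ± 61.1 CPM, Mir429 with 342 ± 6.90 CPM and Mir200c with 287 ± 16.5 CPM. The ciliated list held 0.197% ± 0.0150 with 3 of 5 members detected, namely Mir34c at 1561 ± 44.8 CPM, Mir449a at 348 ± 102 CPM and Mir34b at 54.6 ± 4.45 CPM. The 5 liver and pancreas members held 0.187% ± 0.00119, led by Mir217 with 788 ± 67.0 CPM, Mir375 with 592 ± 22.3 CPM, Mir216b with 314 ± 28.5 CPM and Mir216a with 166 ± 11.7 CPM.

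As counted, the blood, Hox, choroid plexus and muscle lists held the smallest shares. The leukocyte list held 0.0896% ± 0.00296 with 4 of 5 members detected, namely the myeloid microRNA Mir223 with 479 ± 24.4 CPM, Mir155 with 303 ± 9.56 CPM, Mir146 with 87.6 ± 0.238 CPM and Mir150 with 27.4 ± 4.07 CPM. Mir142 was not among the counted genes, and with the opposite-strand reads at its position the leukocyte share would be 0.185% ± 0.00951, next to that of the liver and pancreas list. The 3 erythroid members held 0.0442% ± 0.0303 (0.0657% in replicate 1 and 0.0228% in replicate 2), with 335 ± 314 CPM for Mir451a, 82.3 ± 8.64 CPM for Mir144 and 24.8 ± 1.99 CPM for Mir486. Mir204 and Mir211, of the choroid plexus and pigment epithelium, held 0.0317% ± 0.000420, with 309 ± 7.74 and 8.45 ± 3.54 CPM. The muscle list held 0.0181% ± 0.0137, with 0.0278% in replicate 1 and 0.00839% in replicate 2, where it was below the Hox list at 0.0186%. It had 5 of 9 members detected, among them Mir208b with 118 ± 106 CPM, Mir208a with 28.6 ± 30.3 CPM, Mir206 with 16.9 ± 2.29 CPM and Mir499 with 11.9 ± 0.0511 CPM. The list of microRNAs embedded in Hox clusters, which pattern the trunk and hindbrain, held 0.0179% ± 0.000983 with 4 of 6 detected, namely Mir10a with 112 ± 9.38 CPM, Mir10b with 47.1 ± 2.76 CPM, Mir615 with 9.94 ± 1.28 CPM and Mir196b with 8.98 ± 0.655 CPM. Read counts depend on how well each microRNA ligates to adapters, so levels of different genes are not molar amounts, and members with near-identical copies are uncertain.

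**Figure D1:**
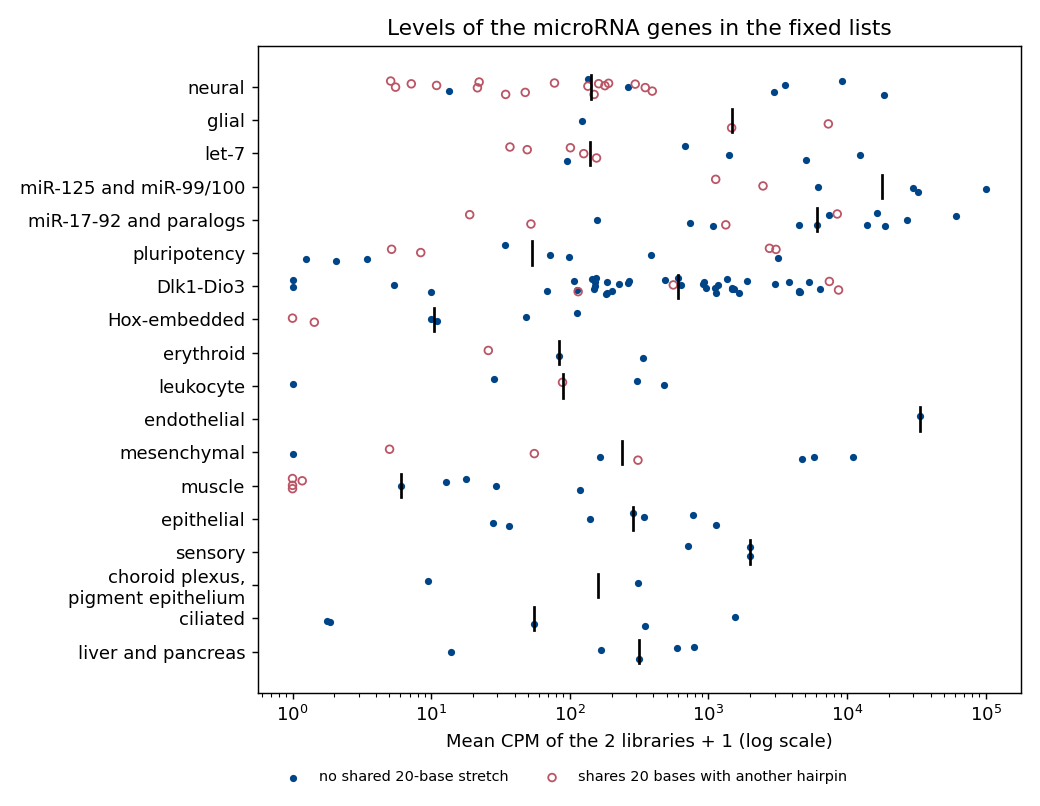
Mean CPM of the 2 libraries plus 1 (log scale) for each measured member of the fixed lists, with filled points for hairpins without a shared stretch of 20 bases, open points for hairpins with one and a black bar at the median of each list. In the neural list the 17 open points have a median of 76.5 CPM and the 7 filled points one of 2954 CPM.

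The remaining comparison between samples was that of the replicates. Mir451a, a microRNA of maturing red blood cells, was 4.71-fold higher in replicate 1 (log2 ratio 2.24, 95% interval 2.10 to 2.37, 1593 against 650 reads, adjusted p = 1.14e-274 by the exact binomial test). The muscle microRNAs Mir208a and Mir208b, in introns of the cardiac myosin genes Myh6 and Myh7, were 6.71-fold and 4.26-fold higher there. Mir5126 was 7.38-fold higher in replicate 2 (log2 ratio -2.88, interval -3.35 to -2.45, adjusted p = 1.71e-65 by the same exact test). Mir2137, Mir6538 and Gm26117 were 6.49-fold, 5.899-fold and 4.43-fold higher in replicate 2, with adjusted p = 2.67e-75, 1.56e-44 and 6.79e-37 by that exact test. These 4 hairpins had a GC content of 83.1% (Mir5126), 60.6% (Mir2137), 75.5% (Mir6538) and 91.6% (Gm26117), and whether their reads come from microRNAs or from fragments of other RNAs such as ribosomal RNA was not tested. The same holds for Mir6240 (named after its values were seen), which was higher in replicate 2 by a log2 ratio of -1.61 (interval -2.004 to -1.232, adjusted p = 1.51e-20 by that exact test) and had a GC content of 47.0%. Most other genes were close, and 384 of the 403 detected genes (95.3%) lay within 2-fold, with a median absolute log2 ratio of 0.22.

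Across these 403 genes, which are not independent replicates, Spearman's rho of the libraries was 0.989 and Pearson's r of log2(CPM + 1) was 0.990. Of 521 genes tested, 208 differed between the libraries by the exact conditional binomial test with Benjamini-Hochberg adjustment, 89 higher in replicate 1 and 119 higher in replicate 2, and 236 passed at an unadjusted p under 0.05. With scaling to total counts 199 differed, 109 higher in replicate 1 and 90 in replicate 2, so the split between directions depended on the scaling. The differences were mostly small, and 26 of the 208 genes differed by 2-fold or more, 13 in each direction. The replicates were not one library deposited again, since the chi-square over genes was 68255.6 on 520 degrees of freedom. The spread beyond counting error, as edgeR's biological coefficient of variation, was 0.220 (bootstrap interval over genes 0.176 to 0.271).

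By list, 28 of the 45 measured Dlk1-Dio3 members differed, 14 in each direction, and 30 when adjusted over the list alone. In the Mir17 list 12 of 15 differed, 9 of them higher in replicate 1, and in the let-7 list 7 of 10, all higher in replicate 2, with the same counts adjusted over the list alone. In the neural list 11 of 24 differed, 7 higher in replicate 1, again 11 adjusted over the list alone. The Mir125 and Mir99 list had 6 of 6, 5 of them higher in replicate 2, and adjusted over the list alone 6. This test compares these libraries, not conditions, and its small p-values reflect deep counts against counting error alone.

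**Figure D2:**
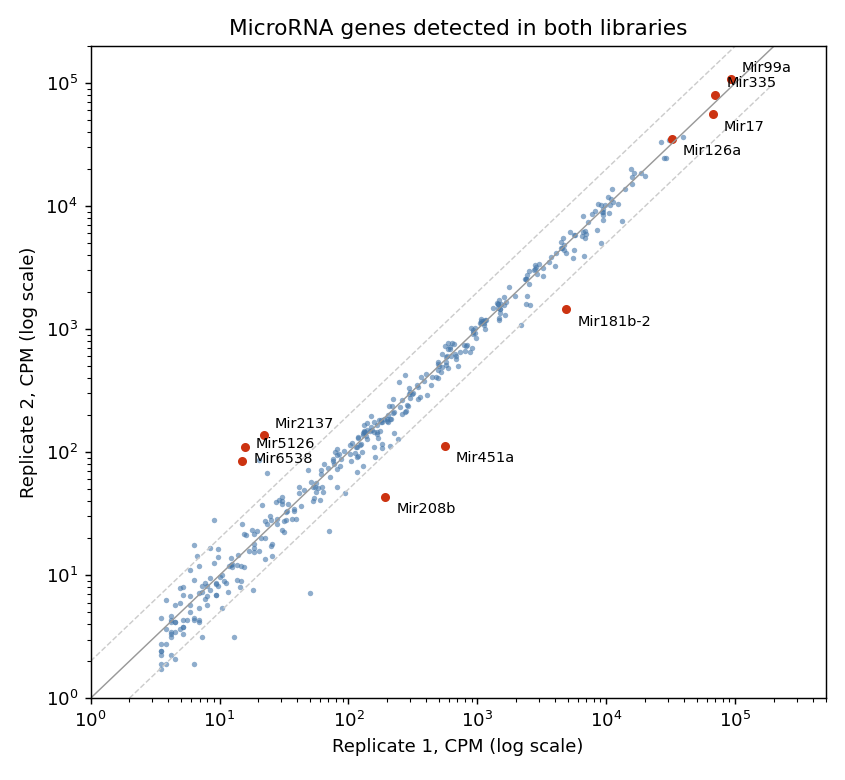
CPM in replicate 1 against CPM in replicate 2 (log scales) for the 403 detected microRNA genes, with the solid line at equal levels, dashed lines at 2-fold and selected genes in red. Mir451a and Mir208b lie below the lower dashed line, and Mir5126, Mir2137 and Mir6538 above the upper one.

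A last comparison asked whether neighbouring hairpins, often cut from a common transcript, had similar levels. The cluster with the most reads lay on chromosome 14 at 115043671 to 115044506 (plus strand, Mir17hg), with 6 hairpins and 11.1% ± 1.27 of the reads (SD, n = 2). Its levels ran from 61380.1 CPM for Mir17 over 26841 CPM for Mir20a, 13871 CPM for Mir18 and 8490.4 CPM for Mir92-1 down to 51.4 CPM for Mir19b-1 (named outside the rule, as the lowest member). This was a 1193-fold range, and 393-fold over the 4 members without a shared stretch. The cluster on chromosome 16 at 77598936 to 77599750 held Mir99a and Mirlet7c-1 with 10.03% ± 1.13 of the reads, and Mirlet7c-1 had 125 ± 9.69 CPM. The third, with 31 hairpins on chromosome 12 at 109709060 to 109747960 in the Dlk1-Dio3 region, held 4.89% ± 0.289, with Mir487b, Mir411, Mir541 and Mir382 (4548 ± 232 CPM) highest.

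Over 114 neighbouring pairs from 158 detected genes in 44 clusters, the median absolute difference was 2.69 on the log2(CPM + 1) scale, or 6.46-fold. Random pairings of the same genes had a median of 3.19, and the middle 95% of 10000 pairings ran from 2.60 to 3.76, which includes the observed value. As low a value arose in 4.48% of random pairings for the mean levels, and in 7.92% and 11.5% in replicates 1 and 2. Greater similarity of neighbours than of random pairs was thus not separable from chance pairing here. Members with a shared stretch, such as Mir19b-1, Mir92-1 and Mirlet7c-1, have uncertain counts.

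**Figure D3:**
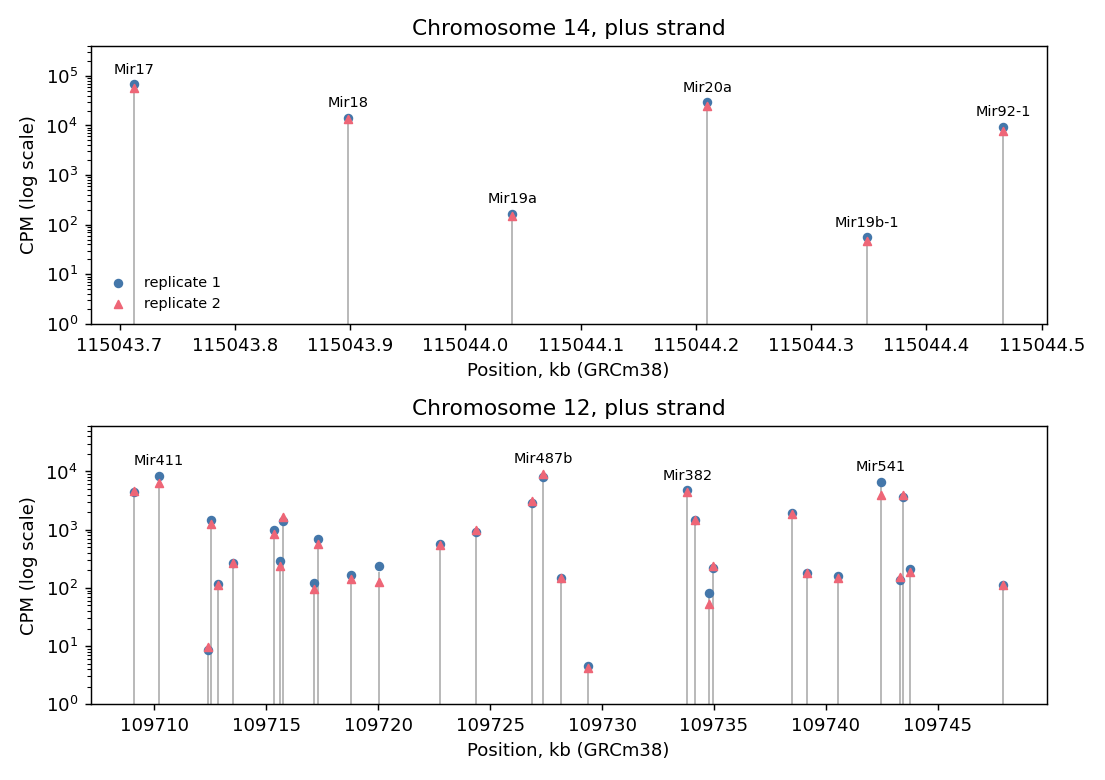
CPM (log scale) of each detected hairpin by position in kb (GRCm38) in the Mir17 cluster on chromosome 14 and the Dlk1-Dio3 cluster on chromosome 12, with circles for replicate 1, triangles for replicate 2 and lines drawn up to the mean. The 6 hairpins of the Mir17 cluster span a 1193-fold range (393-fold over the 4 without a shared stretch), while the replicates of each hairpin lie close together.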

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

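Apart from the planned gene-by-gene comparison of the libraries, the tests in this part were chosen after the results they bear on were seen, and the design, with 1 group, gives no biological contrast to set against them. Counts on the strand opposite to the annotated gene were not used in the comparisons and, with no control samples, were set against the limit of 3 reads. Signals above it with 100 or more reads in each library lay on 9 genes, which held 99.5% of all opposite-strand reads. Summed over both libraries these were 49882 reads at Gm24321, 49771 at Gm25927, 37890 at Gm25252, 33697 at Gm25301, 25106 at Gm24083, 20148 at Mir299b, 10660 at Gm25750, 8508 at Mir142b and 7063 at Mir497b.

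Loss of strand information in the libraries was argued against, since among 147 genes with 1000 or more reads and no microRNA on the other strand the median opposite-strand share was 0% in both libraries. A candidate explanation is that the reads come from microRNAs of the other strand whose own counts were not analysed here, since 99.8% of the opposite-strand reads in each library (99.7809% in the lower) lay on genes that overlap such a microRNA in GENCODE M21. The partners include Mir409 at Gm24321 (chromosome 12, 109743158 to 109743236), Mirlet7e at Gm25927 (chromosome 17, 17830352 to 17830444) and Mir142, a blood cell microRNA, at Mir142b (chromosome 11, 87756864 to 87756927). At the level of these reads Mirlet7e would have 5608 ± 715 CPM and Mir142 1004 ± 69.4 CPM (SD, n = 2), and with such reads the Dlk1-Dio3 share would be 8.06% ± 0.507 (4 partners, Mir409, Mir376a, Mir299a and Mir380), the let-7 share 2.49% ± 0.343 and the leukocyte share 0.185% ± 0.00951, against 6.87%, 2.00% and 0.0896% as counted.

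The neural list as a whole was not low, its detected members lying at the percentiles 48.3 and 45.4 of random lists of detected genes, but its 17 members with a shared stretch had a median of 76.5 CPM against 2954 CPM for the 7 others, a log2(CPM + 1) difference of -5.25 (permutation p = 0.00147, two-sided, over genes, which are not independent replicates). Low levels were argued against for those 7 only, since their median lay at or above the percentile 97.6 of random lists of detected genes without a shared stretch (median 162 CPM) in each library. As the 7 are the high side of the gap, this is not independent of it and does not cover the other 17. Loss of reads from identical hairpin copies stays open: among the 380 detected genes outside the neural list the 79 with a shared stretch differed in their median from the rest by -0.39 on the log2 scale (permutation p = 0.398). Hairpins that lost most of their reads would not be detected and did not enter, so this test cannot decide the question. This test replaced an earlier one on the neural gap itself, which only restates the pattern. The median of the neural members without a shared stretch was 4.16 above that of such detected genes on the log2 scale, against -0.63 for those with one. Detected genes leave out hairpins that lost most of their reads, and the median of all 923 hairpins with a shared stretch was 0 CPM. These values thus cannot tell which side of the gap is the unusual one, and a true difference in level stays open too.

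Mir451a, Mir208a and Mir208b were higher in replicate 1, by log2 ratios of 2.24, 2.75 and 2.09, as was the liver microRNA Mir122 by 1.18 (95% interval 0.58 to 1.80, adjusted p = 0.000301 by the exact binomial test), for which no source was tested. A joint rise of blood cell microRNAs in that tissue was argued against. The other 6 detected erythroid and leukocyte members, none of them on another list, had a median log2 ratio of -0.15. None had an upper 95% bound above 0.20, and the most abundant, Mir223, had 496 and 461 CPM. For red blood cells this rests on the erythroid members Mir144 (-0.28, interval -0.51 to -0.05) and Mir486 (-0.23, interval -0.67 to 0.20). Mir486 shares sequence with another hairpin, and the leukocyte members need not follow red cells. How much Mir144 red cells would add beside Mir451a was not measured, so more red blood cells in replicate 1 are not excluded. Muscle or heart tissue stays open. The abundant muscle microRNAs Mir1a-1, Mir133a-1, Mir133a-2 and Mir133b, which all share sequence with other hairpins, had 1 read in both libraries together and decide nothing. An earlier test on Mir499 and Mir206 was replaced after its result was seen, because their counts are low: their log2 ratios were -0.06 and 0.21, with upper bounds of 0.56 and 0.72, which speaks against a rise as large as that of Mir208a.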

How the results depend on the processing

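Of 47 alternatives, 32 stayed within the spread or count limit of their result, but some of these could not do otherwise. Leaving out a replicate cannot move the share of the 10 highest genes or the neural difference beyond the SD of the 2 libraries. A pseudocount cannot change the ranks behind Spearman's rho. The number 32 is thus no measure of stability. The neural minus other-tissue difference of 0.80 turned to -0.16 with detected members only, where fewer low members enter. The difference was 4.18 without hairpins that share sequence, 0.54 with counts regardless of strand, 0.77 with a pseudocount of 5, and 0.79 to 0.81 leaving out each replicate. Without Mir451a, Mir208a, Mir208b and Mir122 (added after seeing the data) it was 0.65, with 0.81 in replicate 1 and 0.49 in replicate 2. The number of detected genes was 639 with a minimum of 1 read, and 409 to 466 leaving out each replicate. The share of the 10 highest genes was 43.0% with counts regardless of strand, 49.0% without hairpins that share sequence, 40.1% without the highest gene, and 43.5% to 45.0% leaving out each replicate. Leaving out a replicate moved the share of the muscle list to 0.0278% or 0.00839% and that of the erythroid list to 0.0657% or 0.0228%, which changed their order with the Hox and choroid plexus lists. Spearman's rho was 0.9503 over all genes with a read in either library. The number of genes that differed was 26 with a 2-fold minimum, against 208 without it, and total-count scaling turned the split of higher calls from 89 in replicate 1 and 119 in replicate 2 to 109 and 90. The coefficient of variation was 0.168 with 100 or more reads in each library, where low genes are left out. The difference of neighbouring hairpins was 2.38 without hairpins that share sequence and 2.75 to 2.85 leaving out each replicate. The cause was not tested except where a smaller set of genes is named. Simulated 2-fold changes, with counting error only, were called in 33.3% of 36 genes with under 100 reads in sum and 98.4% of 64 with more. No paired analysis was possible because there is 1 group.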

Other observations

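The test of neighbouring hairpins in this part was fixed before its result was seen, and the tests of GC content and the gene groups were chosen after the values were seen. Several families outside the fixed lists were abundant. The 4 members of the Mir130 and Mir301 family held 5.31% ± 0.153 of the reads (SD, n = 2), with 38107 ± 2057 CPM for Mir130a, 11015 ± 1078 CPM for Mir130b and 3636 ± 495 CPM for Mir301. The 6 members of the Mir30 family held 4.30% ± 0.455, led by Mir30e with 26299.6 ± 2401 CPM and Mir30a with 11309 ± 1299.5 CPM. A chosen set of 5 hairpins of imprinted genes outside the Dlk1-Dio3 region held 9.69% ± 0.726. In it Mir335 had 75195 ± 7237 CPM, Mir298 10968 ± 260.4 CPM and Mir296 9957 ± 326 CPM. This share is not a total for imprinted genes, and Mir335 alone held 7.52% of the reads. The X-linked cluster of Mir322 held 2.02% ± 0.0769 over 7 hairpins, with 17384 ± 1548 CPM for Mir322 and 1631 ± 773 CPM for Mir351.

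The Mir181 family, abundant in brain and lymphocytes, held 2.74% ± 0.663 of the reads over 6 members and differed between its copies. Mir181b-2 was higher in replicate 1 by a log2 ratio of 1.70 (95% interval 1.66 to 1.74) and Mir181b-1 by 1.55 (1.23 to 1.88), while the ratios of Mir181a-2 and Mir181a-1 were -0.08 and -0.20. Mir181d had a log2 ratio of 0.75 and Mir181c one of -0.01. These 4 Mir181a and Mir181b hairpins share sequence with other hairpins, so their counts are uncertain.

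A hypothesis was that the differences between the libraries follow the GC content of the hairpins, as a bias of library preparation might. For the bulk of genes the values argue against a trend with the GC content of the whole hairpin, while for the large differences it stays open. The GC content of the sequenced reads, which cover only part of a hairpin, was not examined. Across 297 genes with a mean count of 100 or more, which are not independent replicates, Spearman's rho of the log2 ratio with GC was 0.067 (permutation p = 0.246) while Pearson's r, which gives large ratios more weight, was -0.158. Among the 26 genes that differed by 2-fold or more, the median GC content of those higher in replicate 2 was 22.0 percentage points above that of those higher in replicate 1 (permutation p = 0.0101, two-sided, 13 genes in each direction). These include the GC-rich genes that prompted the comparison, so it restates what was seen and was replaced, after its result was known, by a test on the 14 of them whose GC content had not been looked at. There the difference was 7.09 percentage points (exact permutation p = 0.246, two-sided, 8 genes higher in replicate 2 and 6 in replicate 1), which with so few genes decides nothing. A second hypothesis was that hairpins of a common transcript vary together between tissue pools. Neighbouring hairpins differed in their log2 ratio by a median of 0.17 over 100 pairs, against 0.24 for random pairings, and 0.2% of random pairings were as low. Shared transcription could give this result but was not told apart from likeness of sequence. Some neighbours belong to one family, such as Mir467e and Mir467d, and the random pairings took no account of that. Of the 100 pairs, 6 differed by 1 or more in log2 ratio. These were Mir451a and Mir144 (2.24 and -0.28), Mir181b-2 and Mir181a-2 (1.70 and -0.08), Mir181b-1 and Mir181a-1 (1.55 and -0.20), Mir669e and Mir669l (0.95 and -0.29), Mir351 and Mir503 (0.94 and -0.12), and Mir362 and Mir188 (0.76 and -0.26).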
